A study of Homo sapiens with 4 samples.

How the data were processed

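The material was guide DNA from a pooled CRISPR knockout screen in HAP1, a near-haploid human cell line, carrying a substitution in MTHFD1 (K56R). MTHFD1 is a cytosolic enzyme of folate metabolism that supplies one-carbon units for purine and thymidylate synthesis. Per the labels, cells received the genome-wide Brunello library by lentivirus at a multiplicity of infection near 1 with more than 500 cells per guide intended, were selected with puromycin, and were then grown for 14 days in dialysed medium without or with 50 µM adenosine. Each condition had 2 libraries. Per the labels' protocols, the guide region was amplified from genomic DNA by PCR kept below saturation, gel purified and pooled in equal amounts.

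The deposited values were counts of sequenced reads per guide, listed with a guide identifier and a gene symbol, with no normalization that the values showed. Per the submitters' processing notes, Picard 2.19.2 and the hg38 build were named. The program that assigned reads to guides and its mismatch setting are not given in the sources used here. No molecular identifiers were described. Intervals on shares treat the listed guides as independent draws, and cover neither the counting error of reads nor differences between cultures. The same 77441 guides were listed for every library, of which 1000 were non-targeting controls, and 19107 of 19114 targeted genes had 4 guides. Of the 19114 symbols, 17852 were current in the RefSeq table for GRCh38.p14 and 1135 matched an older symbol of exactly 1 gene. Symbols are printed as the files gave them, and coordinates come from that table.

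Total counts were 69365249 and 68302155 in the control libraries and 79367855 and 68178884 in the adenosine libraries. A count of 0 allowed up to 3 counts, which was between 0.0378 and 0.0440 CPM (counts scaled to the library total). Replicates were told apart from repeat deposits by a chi-square test of their counts, which gave 63.5 per degree of freedom between the controls and 772 between the adenosine libraries. The labels describe duplicate experiments without saying from which step the cultures were kept apart. The p-values of edgeR therefore measure the spread between these libraries, part of which can be technical. Gene p-values from ranks or means of guides set the guides of a gene against random guides instead. In those, differences between cultures enter at most through the guides' own statistics.

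The tests, samples, gene lists, rule for named genes and alternative settings were chosen before the data were examined. Guides with a mean of at least 10 counts over the 4 libraries were tested with edgeR 4.0.16 (quasi-likelihood test, trimmed mean of M-values scaling, group as the sole term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes used a prior count of 2 and are given relative to the median tested guide. That median lay at 0.06 under the main scaling, -0.56 with library totals, 0.25 with DESeq2 size factors and -0.40 with scaling on non-targeting guides. Genes with at least 3 tested guides were tested by robust rank aggregation of the guides' signed edgeR statistics. The p-values came from 10000000 random rank sets of the same size, were two-sided, and were adjusted over all genes. The fold change of a gene is the mean over its guides with the standard error over guides. That error covers differences between guides and leaves out the differences between cultures.

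A fitted fold change compares group means on the count scale, so the library with the higher count weighs more. Each adenosine library was therefore also set against the mean of the controls on its own. For this the log2 of CPM plus 0.1 was taken, and the median non-targeting guide of the library was subtracted.

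The fixed gene lists covered adenosine uptake and purine salvage, de novo purine synthesis, folate and one-carbon metabolism, the methionine cycle, pyrimidine synthesis and salvage, Nudix hydrolases, ADP-ribose and NAD metabolism, adenosine receptors and cAMP signalling, mTORC1 with TSC and GATOR, AMPK and LKB1, p53 and apoptosis, the replication stress response, growth-restraining genes, SWI/SNF with SAGA and the Mediator kinase module, ribosomal proteins of the cytosol and of mitochondria, the proteasome, RNA polymerase II with the spliceosome, and respiratory complex I. Olfactory receptors and non-targeting guides served as null lists. Lists were tested on guides with camera of limma 3.58.1 at a preset correlation of 0.01 against all other guides, two-sided, with Benjamini-Hochberg adjustment over lists.

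The genes named were 11 fixed genes of adenosine, purine and pyrimidine metabolism, the strongest genes past the threshold in each direction, or the 5 of smallest p where fewer than 5 passed, up to 4 members of smallest p per list, and the genes of the 5 single guides of smallest p in each direction. Genes outside this rule are marked as chosen after their values were seen. The tests were tried on simulated counts for the real guides, with 50 genes changed at each fold size. With the spread fitted to all 4 libraries, rank aggregation for adenosine against control recovered 18.0% of genes changed 4-fold, 60.0% at 8-fold and 100.0% at 32-fold among 19097 genes, and the single-guide test recovered 0.0% at 32-fold among 77091 guides. With the spread of the controls, rank aggregation recovered 98.0% at 4-fold among 19098 genes. The simulation gave both adenosine libraries the same fold change and the same spread, which the real ones did not have. Its recovery therefore does not carry over to the data, where the test did not call MTHFD1 at a mean log2 fold change of 5.05.

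Alternatives covered the scaling, the count filter, depth by thinning, the replicate number as a block, DESeq2 1.42.0, counts summed per gene, ranking by fold change alone, the mean fold change against random guide sets, a minimum of 2 guides per gene, a prior count of 0.5, and leaving out each library. With 2 libraries against 2, the smallest two-sided exact permutation p for a single value is 0.33, so no such test is given.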

Results

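Guide abundance was measured in 4 cultures of HAP1 MTHFD1-K56R cells carrying a genome-wide knockout library, 2 grown for 14 days in dialysed medium (control) and 2 in the same medium with 50 µM adenosine. By its title, the series looked for genes tied to resistance against adenosine toxicity in these cells. The files measure guide abundance, not growth or viability. Total counts were 69365249 and 68302155 for control replicates 1 and 2, and 79367855 and 68178884 for adenosine replicates 1 and 2. The median guide had 765 and 740 counts in the controls, 295 in adenosine replicate 1 and 653 in adenosine replicate 2.

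Guide representation differed most in adenosine replicate 1. The Gini index, which is 0 when all guides are equally abundant, was 0.349 and 0.373 in the controls, 0.759 in adenosine replicate 1 and 0.475 in adenosine replicate 2. The most abundant 1% of guides held 3.34% and 3.59% of counts in the controls, 19.9% in adenosine replicate 1 and 5.51% in adenosine replicate 2. Guides with fewer than 10 counts numbered 415 and 435 in the controls, 10178 in adenosine replicate 1 and 854 in adenosine replicate 2. Guides at 0 counts made up 0.359% of the listed guides in control replicate 1 (95% Wilson interval 0.319 to 0.404) and 0.381% in control replicate 2 (0.340 to 0.427). The share was 0.768% in adenosine replicate 1 (0.709 to 0.832) and 0.458% in adenosine replicate 2 (0.413 to 0.509). Across guides, which are not independent replicates, the Pearson correlation of log2 CPM was 0.784 between the controls and 0.467 between the adenosine libraries. Control replicate 2 and adenosine replicate 2 correlated at 0.797.

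**Figure D1:**
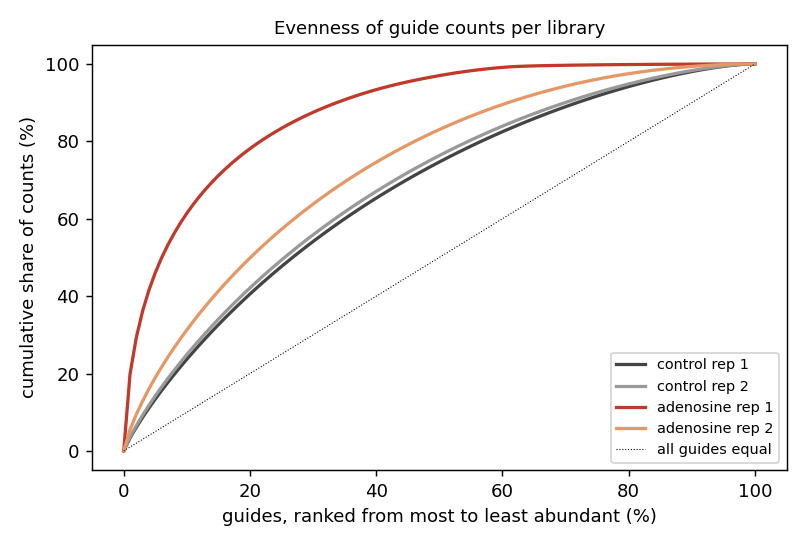
Cumulative share of counts (%) against guides ranked from most to least abundant (%), with 1 line per library and a dotted line for equal abundance. The most abundant 1% of guides held 19.9% of counts in adenosine replicate 1 and between 3.34% and 5.51% in the other libraries.

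The comparison of adenosine with control asked which knockouts became more or less common under adenosine. Guides against NUDT5, MTHFD1 and HPRT1 stood above the controls in both adenosine libraries, for all 4 guides of each gene. NUDT5 encodes a Nudix hydrolase that acts on ADP-ribose. HPRT1 encodes the enzyme that salvages hypoxanthine and guanine. MTHFD1 is the folate enzyme that already carried the substitution in these cells. The mean guide log2 fold change was 4.94 ± 0.54 (SE, n = 4 guides) for NUDT5, 5.05 ± 0.38 (SE, n = 4 guides) for MTHFD1 and 4.62 ± 0.23 (SE, n = 4 guides) for HPRT1. These values were 2.86, 2.16 and 1.99 without adenosine replicate 1, and 6.10, 6.36 and 5.90 without adenosine replicate 2.

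In counts scaled to library totals (CPM), the mean NUDT5 guide had 18.8 ± 0.413 in the controls (SD, n = 2 libraries), 593 in adenosine replicate 1 and 107 in adenosine replicate 2. The mean MTHFD1 guide had 23.7 ± 1.41 in the controls (SD, n = 2 libraries), 615 in adenosine replicate 1 and 91.8 in adenosine replicate 2. The mean HPRT1 guide had 25.4 ± 2.05 in the controls (SD, n = 2 libraries), 470 in adenosine replicate 1 and 87.0 in adenosine replicate 2. The weakest NUDT5 guide by count went from 429 and 240 counts in the controls to 2428 and 2389 in the adenosine libraries. In GRCh38.p14 NUDT5 lies on chromosome 10 from 12165330 to 12195891, MTHFD1 on chromosome 14 from 64388353 to 64460025, and HPRT1 on chromosome X from 134460165 to 134500668, and all 3 are protein-coding genes.

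Relative to non-targeting guides, the log2 ratio of NUDT5 to the control mean was 4.83 ± 0.64 (SE, n = 4 guides) in adenosine replicate 1 and 2.64 ± 0.27 in adenosine replicate 2. MTHFD1 stood at 5.07 ± 0.38 and 1.93 ± 0.34, and HPRT1 at 4.62 ± 0.25 and 1.76 ± 0.14, in the same order. Of 19098 genes, MTHFD1 ranked 1, NUDT5 ranked 2 and HPRT1 ranked 3 by this ratio in adenosine replicate 1. In adenosine replicate 2 the order was NUDT5, MTHFD1, HPRT1. The size of the ratio differed between the adenosine cultures by more than the standard error over guides for each of the 3 genes.

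**Figure D2:**
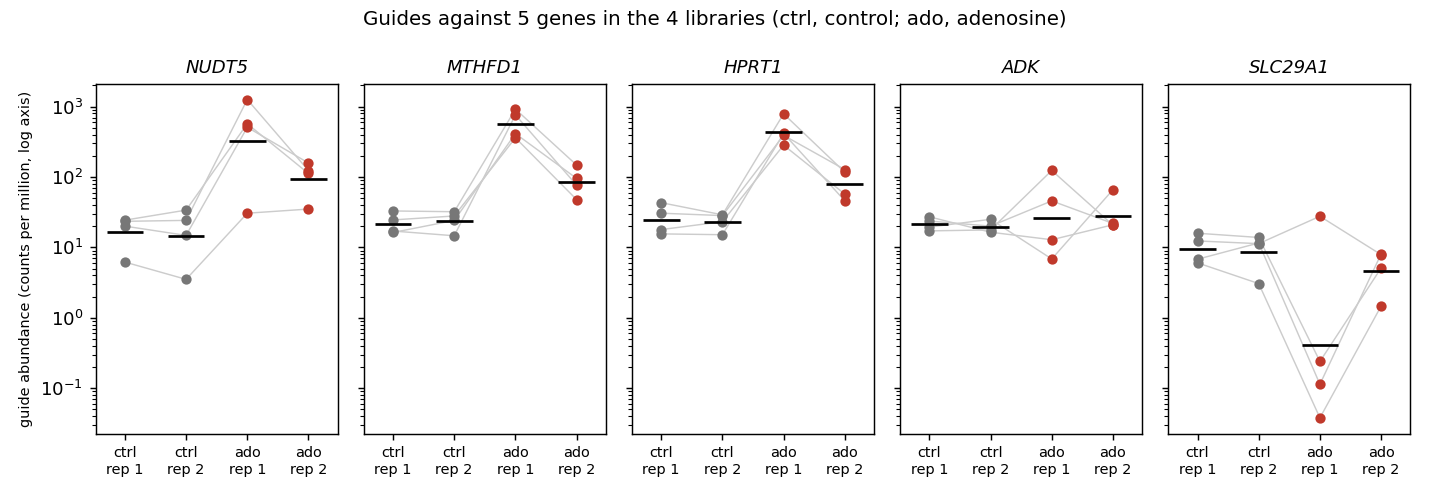
Abundance of single guides (CPM, log axis) against 5 genes in the 4 libraries, with grey lines joining each guide and black bars for the geometric mean of 4 guides. Guides of NUDT5, MTHFD1 and HPRT1 lie above both controls in both adenosine libraries, while guides of ADK and SLC29A1 spread in both directions in adenosine replicate 1.

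By the planned gene test, robust rank aggregation of edgeR statistics, 0 genes rose and 0 fell among 19098, with 552 higher and 579 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.210. The adjusted p of that test was 0.570 for NUDT5, 1.0 for MTHFD1 and 0.974 for HPRT1. Ranking guides by fold change alone called 3 genes, which were these 3, at an adjusted p of 0.00509 each. The permutation test of the mean fold change against random guide sets called the same 3 at an adjusted p of 0.00127 each. Both of these tests set guides against random guides, so variation between the adenosine cultures was not part of them. Over all alternatives the adjusted p ran from 0.00127 to 0.974 for NUDT5 and from 0.00127 to 1.0 for MTHFD1 and HPRT1. With adenosine replicate 1 left out, rank aggregation called the same 3 genes and 0 lower ones, and with adenosine replicate 2 left out it called the same 3 and 2 lower ones, RPP14 and RPP21 (named after their values were seen). In those fits the spread came from the 2 controls alone, so variation between adenosine cultures was not part of the test. Counts summed per gene and tested with edgeR called 0 genes, with 232 higher and 94 lower at an unadjusted p under 0.05. Together these were fewer than chance alone would give at that p.

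For single guides, edgeR called 0 higher and 0 lower among 77128, with 1854 higher and 301 lower at an unadjusted p under 0.05. Together these were fewer than chance alone would give at that p. The imbalance depended on the scaling. It was 283 higher and 311 lower with library totals, 467 and 299 with scaling on non-targeting guides, and 2928 and 381 with DESeq2 size factors. DESeq2 called 3480 higher and 0 lower, but gave no adjusted p for 67290 guides, so most guides could not be called in either direction. At an unadjusted p under 0.05 the DESeq2 Wald test had 7617 higher and 3302 lower. Without adenosine replicate 1 edgeR called 3431 guides higher and 1419 lower, and without adenosine replicate 2 it called 22013 higher and 31519 lower, again with the spread taken from the controls alone. The single guides of smallest p were against TEX15, MYH6, NUDT5, ZNF37A and PGLS among the higher ones, and against PRAP1, SIX2, ADAM17, MASP1 and SPATA13 among the lower ones, with an edgeR adjusted p of 0.874 for each. The NUDT5 guide among them had a log2 fold change of 3.57.

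Other genes of adenosine and nucleotide metabolism passed no gene test. ADK, the kinase that turns adenosine into AMP, had a mean guide log2 fold change of 1.57 ± 0.62 (SE, n = 4 guides), with ratios of 0.80 in adenosine replicate 1 and 0.49 in adenosine replicate 2. SLC29A1, an equilibrative nucleoside transporter, had -0.95 ± 0.94, with 1 of 4 guides above the controls in adenosine replicate 1. PPAT, which catalyses the first committed step of purine synthesis, had -0.999 ± 0.73, and APRT, which salvages adenine, had -0.97 ± 0.87. Each adenosine library gave its own size, with ratios in replicates 1 and 2 of -3.23 and -0.89 for SLC29A1, -2.58 and -0.95 for PPAT, and -2.50 and -0.83 for APRT. Without adenosine replicate 1 the fold changes of ADK, SLC29A1, PPAT and APRT were 0.72, -0.70, -0.76 and -0.67, and without adenosine replicate 2 they were 2.08, -2.60, -1.51 and -1.57. ADA, which deaminates adenosine, had -0.03 ± 0.59, and its sign turned with the scaling, to 0.072 with library totals and 0.040 with scaling on non-targeting guides. PNP had 0.41 ± 0.50, AHCY 0.29 ± 0.90 and UMPS 0.25 ± 0.25, and none of these had a settled sign. Relative to non-targeting guides, the ratios in adenosine replicates 1 and 2 were -1.54 and 0.46 for PNP, -1.41 and -0.44 for AHCY, and -0.42 and -0.36 for UMPS. These ratios, and those of ADK, SLC29A1, PPAT and APRT, count from non-targeting guides. On that scale the median gene-targeting guide differed from the control mean by -1.12 in adenosine replicate 1 and -0.16 in adenosine replicate 2. A ratio near those values is therefore no loss relative to other genes. In adenosine replicate 1 PNP ranked 9558, AHCY 8836 and UMPS 3985 of 19098 genes, counted from the highest ratio. Without adenosine replicate 1 the fold change was -0.21 for AHCY and -0.15 for UMPS, and without adenosine replicate 2 it was -0.33 for AHCY and -0.50 for PNP. The smallest adjusted p that any of these 8 genes reached in an alternative was 0.758, for ADK.

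The 5 higher genes of smallest p under rank aggregation were KIAA0101, TUFT1, ZFHX3, MGA and AFF4, with adjusted p between 0.210 and 0.390. Their mean guide log2 fold changes were 2.69 ± 0.28 for KIAA0101, 3.31 ± 0.86 for TUFT1, 1.90 ± 0.65 for ZFHX3, 3.24 ± 1.34 for MGA and 3.02 ± 0.51 for AFF4. In adenosine replicate 2 the ratio was 0.051 for KIAA0101, 0.56 for TUFT1, 1.08 for ZFHX3, 0.077 for MGA and 0.12 for AFF4. The fold changes without adenosine replicate 1 were 0.25 for KIAA0101, 0.94 for TUFT1, 1.31 for ZFHX3, 0.31 for MGA and 0.34 for AFF4. The 5 lower genes were CCL15, RUVBL1, RPL24, RAD50 and TRIM64, with adjusted p between 0.383 and 0.390. Their mean guide log2 fold changes were -2.37 ± 1.20 for CCL15, -2.96 ± 0.70 for RUVBL1, -2.79 ± 0.21 for RPL24, -2.97 ± 0.36 for RAD50 and -1.64 ± 1.58 for TRIM64. With counts summed per gene, CCL15 stood at -0.32 and TRIM64 turned to 0.40, and each had 1 of 4 guides above the controls in adenosine replicate 1. RAD50, a subunit of the complex that senses DNA breaks, had ratios of -4.63 in adenosine replicate 1 and -2.32 in adenosine replicate 2. RPL24, a protein of the large ribosomal subunit, had -4.40 and -2.04. In adenosine replicate 1 the mean guide had 0.12 CPM for RAD50 and 0.094 for RPL24, near the 0.1 CPM added before the log2. The size of the ratios in that library is therefore limited by this floor and by the control level.

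**Figure D3:**
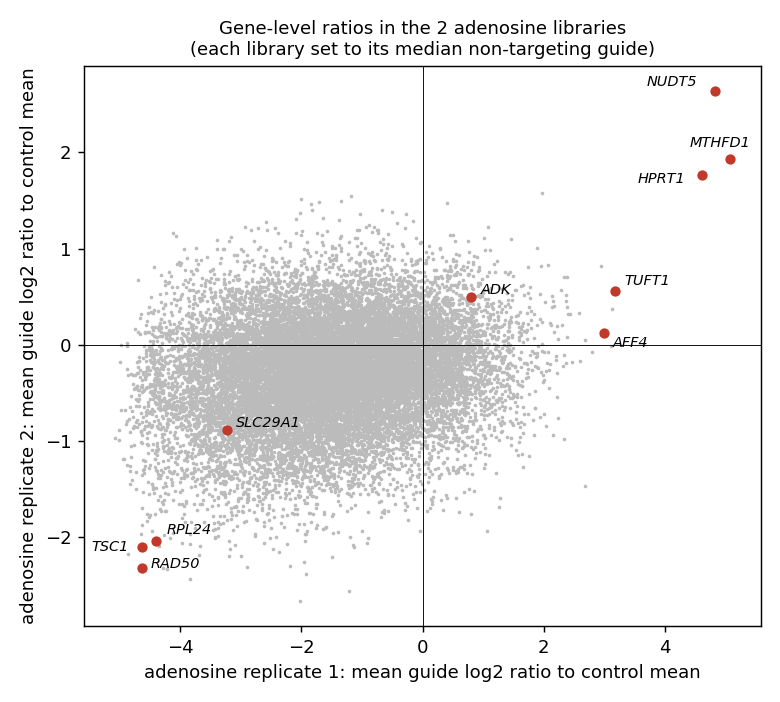
Mean guide log2 ratio to the control mean in adenosine replicate 1 (horizontal) and adenosine replicate 2 (vertical), 1 point per gene, each library set to its median non-targeting guide. NUDT5, MTHFD1 and HPRT1 lie apart at the upper right, at 4.62 to 5.07 in adenosine replicate 1 and 1.76 to 2.64 in adenosine replicate 2.

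Guides against 4 lists of growth-related machinery fell relative to other guides in the fit of all libraries at a preset correlation. These calls rested on adenosine replicate 1 and were lost with an estimated correlation, at an adjusted p = 0.909 each. The shift of the mean log2 fold change was -0.89 for 78 cytosolic ribosomal protein genes (camera adjusted p = 2.0e-07) and -0.79 for 36 genes of RNA polymerase II and the spliceosome (adjusted p = 1.1e-05). It was -0.56 for 31 proteasome genes (adjusted p = 0.00489) and -0.54 for 22 genes of the replication stress response (adjusted p = 0.0108). Guides against 49 genes of respiratory complex I rose by 0.40 relative to other guides (adjusted p = 0.0232), and the 994 tested non-targeting guides by 0.68 (adjusted p = 2.0e-07). These 2 calls were likewise lost with an estimated correlation, at an adjusted p = 0.909. Non-targeting guides were a null list, yet passed camera at the same adjusted p as the ribosomal proteins, 2.0e-07. Olfactory receptors, the other null list, did not pass (camera adjusted p = 0.670). A call at the preset correlation therefore does not by itself mark an effect of knocking out the genes of a list.

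The lower lists were low mainly in adenosine replicate 1. Relative to non-targeting guides, the median ribosomal protein guide was at -1.57 and -1.58 log2 in the controls, -5.93 in adenosine replicate 1 and -2.02 in adenosine replicate 2. The median guide of RNA polymerase II and the spliceosome was at -1.46 and -1.42 in the controls, -5.82 in adenosine replicate 1 and -1.70 in adenosine replicate 2. The median proteasome guide was at -1.57 and -1.25, then -5.52 and -1.36. Olfactory receptor guides, a null list, were at -1.18 and -1.06, then -2.10 and -1.13. The median complex I guide was at -1.38 and -1.47 in the controls and at -1.46 and -1.49 in the adenosine libraries. Without adenosine replicate 1 the shift was -0.36 for ribosomal proteins, -0.18 for RNA polymerase II and the spliceosome, 0.039 for the proteasome, -0.14 for replication stress, 0.076 for complex I and 0.31 for non-targeting guides, and none of the 6 was called. Without control replicate 2 the calls of replication stress (-0.44) and complex I (0.36) were also lost.

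Within the called lists, 0 genes passed over all genes tested. Adjusted over the list alone, rank aggregation called RPL24 among the ribosomal proteins (adjusted p = 0.0132) and 0 genes in the other lower lists. The permutation test of the mean, adjusted over the list alone, called RPL12, RPL23, RPL24, RPL36 and RPS20 lower, which were 5 of 78. It also called SNRNP200 and U2AF2, both of the spliceosome, lower and POLR2H higher. RPL36 and POLR2H were named after their values were seen. SNRNP200 had a mean guide log2 fold change of -2.55 ± 0.84 and U2AF2 -2.44 ± 0.41. The 2 other lower lists had 0 such genes, with PSMA7 at -1.69 ± 0.54 and PSMA5 at -1.21 ± 0.27 in the proteasome, and RNASEH2C at -2.01 ± 0.55 and TOPBP1 at -1.30 ± 0.18 in replication stress. Without adenosine replicate 1 these 4 genes were at -0.82, -0.21, -1.30 and -0.55, and without adenosine replicate 2 at -3.79, -3.82, -3.29 and -2.89, in the same order. SNRNP200 was at -1.69 and -4.36 in these fits. PSMB7 and PSMD4, also among the proteasome genes of smallest p, were at -0.32 ± 1.38 and -0.69 ± 1.12 in the fit of all libraries. They had 2 and 1 of 4 guides above the controls in adenosine replicate 1. The mean guide fold change was above 0 for 5 of 31 proteasome genes and 5 of 22 replication stress genes. Among the latter was CDK2, at 1.20 ± 0.82, and at 0.15 without adenosine replicate 1. In complex I, 35 of 49 genes had a mean guide fold change above 0 and 0 passed. NDUFA8 was at 1.58 ± 0.41 and NDUFB10 at 1.33 ± 0.27, while NDUFB4 was at -0.20 ± 1.41. NDUFB10 was at 0.61 without adenosine replicate 1 and 2.20 without adenosine replicate 2.

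**Figure D4:**
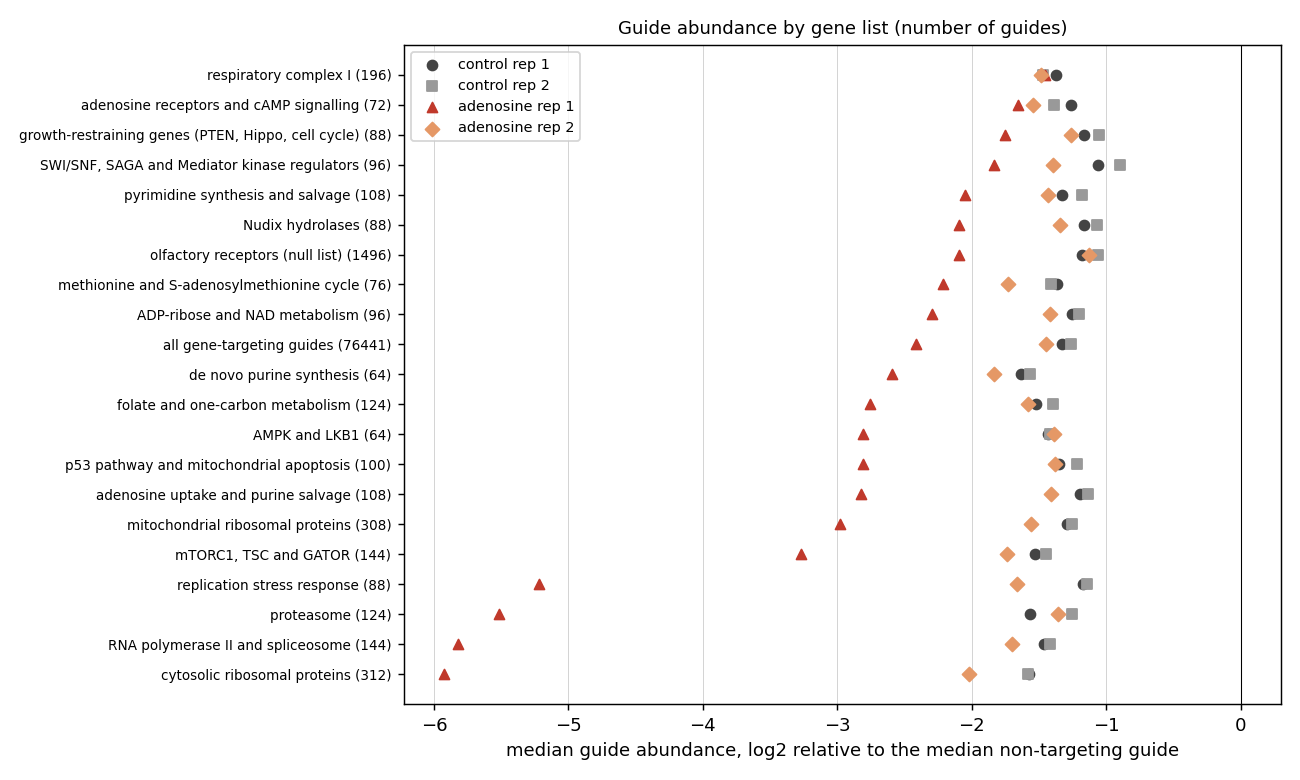
Median guide abundance of each gene list (log2 relative to the median non-targeting guide of the same library), with 1 symbol per library and the number of guides in parentheses. In adenosine replicate 1 the ribosomal protein, RNA polymerase II and spliceosome, proteasome and replication stress lists lie between -5.93 and -5.21, while complex I lies at -1.46.

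The metabolic lists as groups did not pass the camera test, and their shifts were small. The shift was -0.03 for adenosine uptake and purine salvage, -0.04 for de novo purine synthesis, 0.05 for folate and one-carbon metabolism, 0.16 for the methionine cycle, 0.07 for pyrimidine synthesis and salvage, 0.24 for Nudix hydrolases and -0.05 for ADP-ribose and NAD metabolism. Adjusted over the list alone, rank aggregation called NUDT5 among 22 Nudix hydrolases (adjusted p = 0.0263) and 0 genes in the other metabolic lists. The permutation test of the mean, adjusted over the list alone, called HPRT1 among 27 purine salvage genes, MTHFD1 among 31 folate genes and NUDT5. The test and the mean differed in sign for de novo purine synthesis and for ADP-ribose and NAD metabolism, which camera placed upward. The mean and the median guide differed in sign for folate metabolism (median -0.05) and Nudix hydrolases (median -0.10).

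The signalling and chromatin lists did not pass camera either. The shift was 0.08 for adenosine receptors and cAMP signalling, -0.24 for mTORC1 with TSC and GATOR, -0.15 for AMPK and LKB1, -0.10 for p53 and apoptosis (median guide 0.02), 0.32 for growth-restraining genes, -0.02 for SWI/SNF, SAGA and the Mediator kinase module (median guide 0.02), and -0.32 for mitochondrial ribosomal proteins. Olfactory receptors had a shift of 0.15 (adjusted p = 0.670). Against random lists matched on mean count, the median gene of the mTORC1 list, at -0.51, was low with an adjusted permutation p of 0.0327. That test takes no account of correlation between guides, and camera gave this list an adjusted p = 0.909 with an estimated correlation. Relative to non-targeting guides, the median guide of this list differed from the control mean by -1.78 in adenosine replicate 1 and -0.25 in adenosine replicate 2, against -1.12 and -0.16 for all gene-targeting guides. The permutation test of the mean, adjusted over the list alone, called TSC1, a subunit of the complex that restrains mTORC1, at -2.92 ± 0.67, and PRKAG1, a subunit of AMPK, at -2.82 ± 0.68. Rank aggregation adjusted over the list alone called neither, with a smallest adjusted p of 0.0982 in the mTORC1 list and 0.0930 in the AMPK list, and over all genes the permutation test of the mean gave an adjusted p of 0.184 for TSC1 and 0.215 for PRKAG1. TSC1 was at -2.03 without adenosine replicate 1 and -4.66 without adenosine replicate 2. CDKN2A, which restrains the cell cycle, had 1.73 ± 0.51, with all 4 guides above the controls in both adenosine libraries and a rank aggregation adjusted p of 0.668. It was at 0.80 without adenosine replicate 1 and 2.61 without adenosine replicate 2.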

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

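The limma-voom fit with library quality weights was chosen after the data were seen, and the other alternatives were planned. The counts of called guides and genes stayed at 0 under library totals, DESeq2 size factors, scaling on non-targeting guides, both count filters and thinning, and the gene counts also with at least 2 guides per gene. Over the alternatives, 900 values of named genes kept their direction and side of the threshold, 18 passed the threshold and 18 turned direction. Part of the 900 was fixed in advance. Settings that changed the gene test alone reused the main fold changes, and the prior count and the median over guides reused the main call. Of the gene list values, 256 kept their call or stayed uncalled, the latter whatever their direction. Guides called higher numbered 3480 with DESeq2. Leaving out a library gave 0 to 22013 guides higher and 0 to 31519 lower. Genes called higher numbered 3 when guides were ranked by fold change alone, 3 with the mean against random guide sets and 3 with limma-voom, which also called 1 lower, GATC (named after its value was seen). Leaving out a library gave 0 to 3 genes higher and 0 to 2 lower. With either adenosine library left out, the spread came from the 2 controls alone and the lone adenosine library was assumed to vary as they did, so those counts leave out variation between adenosine cultures.

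The replicate numbers were checked as pairs, and the deviations of same-numbered libraries correlated at 0.102 over 2 pairs, which does not establish pairing. With the replicate block, 0 guides and 0 genes were called in each direction.

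Directions turned for genes with small or uneven changes, and the cause was not tested. ADA was at 0.072 with library totals, 0.040 with non-targeting scaling, 0.019 with the replicate block and 0.060 with summed counts, and at -0.62 to 0.48 with a library left out. AHCY was at -0.19 with the replicate block, -0.19 with limma-voom, -0.21 as the median over guides, and -0.33 to 0.29 with a library left out. With summed counts GATC was at 2.99, TRIM64 at 0.40 and UMPS at -0.22. With a library left out, PNP ran from -0.50 to 0.78, UMPS from -0.15 to 0.83, RPP14 from -2.54 to 0.061 and RPP21 from -3.98 to 0.032.

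With an estimated correlation the list calls were lost at unchanged shifts of -0.54 for replication stress, -0.89 for ribosomal proteins, -0.56 for the proteasome, -0.79 for RNA polymerase II and the spliceosome, 0.40 for complex I and 0.68 for non-targeting guides. With a library left out these ran from -1.24 to -0.14, -1.76 to -0.36, -1.64 to 0.039, -1.79 to -0.18, 0.076 to 0.98 and 0.31 to 1.66. Complex I was also lost with library totals, at 0.29. The mTORC1 list was called against matched random lists alone, at -0.51, and had an adjusted p = 0.909 with an estimated correlation. The cause of these changes was not tested. The Gini index of adenosine replicate 1 was 0.760 after thinning, which removes few counts per guide and so tests little. The guide GC correction and the count of guides matching several genes were not run, because guide sequences were not analysed here.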

Other observations

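All tests in this part were chosen after the results were seen. Genes at either end of both adenosine libraries were counted on the ratio to the control mean, and those named here outside the rule were chosen after their values were seen. Of the 191 highest genes (1%) in each library, 6 were shared, namely NUDT5, MTHFD1, HPRT1, IFIT3, PLGLB1 and ZNF37A. Independent lists would share 1.91. A simulation of 100 runs shuffled guide ratios over guides and subtracted a shared draw of control noise, a noise the ratios already held. It gave 2.76 on average and 7 at most. It also untied each ratio from the guide's control level, which with the added 0.1 CPM limits how low a ratio can go. The simulated overlap of lowest genes may therefore be too small. It keeps no likeness between guides of a gene, so an excess over it can reflect any gene-level pattern, not adenosine alone. Of the 191 lowest genes, 11 were shared, against 3.14 on average and 9 at most in the simulation. They were RAD50, SMC3, SPC25, DONSON, CDC26, SRSF6, TSC1, C16orf72, CTSG, HDGFRP3 and TMEM2. Their ratios in adenosine replicate 1 lay between -4.85 and -4.47. The mean guide of RAD50 and of TSC1 had 0.12 and 0.069 CPM there, near the 0.1 CPM added before the log2. With a separate control for each adenosine library, 11 or 5 lowest genes were shared, depending on which control went with which library, and part of the excess can come from the shared controls. The covariance of the ratios across genes was 0.123 against a simulated 0.0316, and 0.118 or 0.0646 with separate controls.

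Non-targeting guides were more abundant than gene-targeting guides in every library. The median gene-targeting guide lay at -1.33 and -1.26 log2 relative to the median non-targeting guide in the controls, -2.41 in adenosine replicate 1 and -1.45 in adenosine replicate 2. Counts of the starting library were not analysed here, so these are levels and not changes over time.

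NUDT5, MTHFD1 and HPRT1 guides stood above the controls in both adenosine libraries. Chance outgrowth of single guides is argued against, because 1 of 1000 shuffles of guides over genes held a gene whose lowest of 8 ratios reached the lowest of the 3 genes (0.90 for MTHFD1), and the next gene in the data, CCDC7, reached 0.44. An advantage shared by all cultures cancels in a ratio to the controls, unless the adenosine cultures divided more often. This was not tested and stays open. The low growth-related guides of adenosine replicate 1 (-3.03 log2, weighed below) may reflect more divisions there, against -0.23 in adenosine replicate 2. Relative to non-targeting guides, the controls had -0.34 and -0.12 log2 for MTHFD1, -0.16 and -0.15 for HPRT1, and -0.75 and -0.83 for NUDT5. The median gene-targeting guide lay lower there, at -1.33 and -1.26. Without starting-library counts, these levels cannot show whether losing the 3 genes helped the controls. A candidate explanation is that loss of these genes lets cells tolerate adenosine, a hypothesis from these 4 libraries that no test here addressed.

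Guides spread far more widely in adenosine replicate 1 than in the other libraries. Lower depth is argued against, since this library had the highest total, 79367855 counts. The spread (SD) of non-targeting log2 ratios was 3.90 times that between the controls, and 1.37 to 1.68 times in adenosine replicate 2. In cells with a single guide, this argues against knockout effects alone. At a multiplicity of infection near 1, a non-targeting guide can share a cell with a knockout guide. The comparison therefore cannot exclude knockout effects. A narrowed cell population, less genomic DNA in the PCR or uneven amplification may each account for the wide spread, and no value here separates them.

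Guides against ribosomal proteins, RNA polymerase II, the spliceosome and the proteasome were very low in adenosine replicate 1 alone. Random loss acting alike on all guides is argued against, since the median of the 580 guides lay at -3.03 log2 relative to olfactory receptor guides of the same control level (95% bootstrap interval -3.40 to -2.64). An effect of adenosine of like size in both adenosine cultures is argued against, since the same difference was -0.23 in adenosine replicate 2 (-0.40 to -0.01). Both intervals came from resampling 145 genes within a library, so neither covers differences between cultures. A smaller effect in adenosine replicate 2 stays open. More cell divisions, or more complete knockout, in adenosine replicate 1 than in the other 3 cultures may account for it and was not tested. In control replicates 1 and 2 and adenosine replicate 2 the median ribosomal protein guide lay at -1.57, -1.58 and -2.02 log2. Olfactory receptor guides lay at -1.18, -1.06 and -1.13, all relative to non-targeting guides. That gap was small next to the one in adenosine replicate 1. Growth defects may have shown little in those 3 cultures, so an uncalled gene is weak evidence of no effect.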
